A study of Mus musculus with 12 samples.

How the data were processed

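The data are mRNA profiles of colon from 12 wild-type C57BL/6J mouse samples. Per the labels, RNA was purified with an RNeasy mini plus kit, and libraries were made from total RNA with a SMARTER mRNA-Seq kit. Per the labels, the genome build was mm10. The aligner, the counting tool, the annotation release and the filters are not given in the sources used here.

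The authors deposited 1 table of FPKM values (fragments divided by gene length and by a library size), with 1 column per sample and 54532 genes named by Ensembl identifier. Of these genes, 23672 were at 0 in every sample and 17497 were above 0 in all 12 samples. Symbols and coordinates came from the GENCODE M21 annotation of mm10, and 54409 identifiers had a symbol there. Column names matched the sample labels by group and replicate number.

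FPKM divides out a library size but leaves its imprint. Low values stepped in whole multiples of 1 value per gene and library, so fragments were recovered from the FPKM and the summed exon length of each gene. In each library 97.0% to 97.2% of values came out whole within 0.1 fragment. The recovered fragments over genes ranged from about 14700000 to 17900000 per library, and the library sizes that the FPKM were divided by from about 13500000 to 19100000. These sizes are not plain totals, as that of CD+DSS replicate 2 was about 13500000 against about 16000000 fragments over genes. The median ratio of each library to the geometric mean over genes above 0 in all samples was 1.009 in every library. The deposited FPKM therefore already carried a scaling to equal median ratios, which no label mentions. A comparison of FPKM between libraries rests on that scaling, in which the median gene does not move.

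The treatment labels gave 4 groups of 3 samples, which are CD, HFD, CD+DSS and HFD+DSS. Replicate pairs within a group differed by far more than counting noise, so no library was treated as deposited more than once. Nothing in the labels says that the 3 samples of a group came from separate animals, cages or days. The p-values therefore measure the spread between these samples.

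Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend over mean expression). Genes at FPKM 1 or more in at least 3 of the 12 samples were tested, which left 14179 genes. All 12 samples entered 1 fit with a mean per group and no covariate. The contrasts were DSS within each diet, diet without DSS, diet with DSS, diet averaged over DSS, and the interaction, which is the DSS effect under HFD minus that under CD. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and each is given with its standard error (SE) from limma. Group values are mean FPKM ± SD with n = 3. Chance alone would give 709 genes at an unadjusted p under 0.05 per contrast.

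Gene lists numbered 37, with 709 entries of which 625 were tested. They covered autophagy machinery, lysosome, bile acid genes, cytokines, chemokines, immune and epithelial cell types, stem and proliferation genes, junctions, defence, wound-associated epithelium, matrix, smooth muscle, enteric neurons and glia, endothelium, adipocytes, exocrine pancreas, lipid metabolism, interferon, MHC class II, the unfolded protein response, hypoxia, NRF2 targets, respiratory chain, mitochondrially encoded genes, haemoglobin, the circadian clock and sex-specific genes. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over the 37 lists within a contrast. Camera with a correlation estimated from the data was run beside it and called 0 lists in every contrast. The preset value therefore decides every list call given here. Limma's fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, was the other set test.

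Genes were named by a fixed rule. It took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose higher group had a mean FPKM of 5 or more, without predicted genes and receptor segments. It also took up to 4 members of each list with the smallest p, 16 genes of inflammation, autophagy and bile acid sensing, and the 8 smallest p of the interaction and of the averaged diet contrast. Where a contrast called fewer than 5 genes, its 5 smallest p were taken as not called. Other genes were named outside this rule. The posterior Hox genes Hoxa13, Hoxb13 and Hoxd13 and the 6 adipocyte genes of the fat tissue test were chosen after the list results but before their own values in each library had been seen. Hoxb6, Sbno2 and the gene sets of the other tests in the closing section were chosen after values had been seen. Genes with near-identical copies, such as Hspa1a with Hspa1b, Reg3g with Reg3b, the Clca4 and Ly6 families and the ribosomal pseudogenes, may share fragments, and their values are uncertain to that extent. How fragments that overlap genes on opposite strands were assigned is not given in the sources used here.

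The groups, contrasts, tests, gene lists, naming rule and the other settings tried were chosen before the data were examined. These settings were a pseudocount of 0.1, no filter, a stricter filter, quantile normalization, median-ratio scaling, a replicate term, other variance models, a 2-fold threshold, the 2 compared groups alone, leaving out each library, and the other set tests. Settings added after the data were seen were voom on the recovered fragments, sample weights, smooth muscle level as a covariate, posterior Hox level as a covariate, and the contrast of DSS averaged over diets. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

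The fit was tested on simulated data for HFD+DSS against CD+DSS over 14179 genes. It recovered 68 of 100 genes changed by a log2 fold of 1 and 95 of 100 changed by 2, with 10 false calls. It made 0 calls in a contrast that was left unchanged. The simulated genes varied independently of each other with normal noise, and the changed genes were drawn from the more highly expressed ones. Variation that genes share across libraries was not simulated, so these figures do not give the recovery in the real data or for low genes.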

Results

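Colon mRNA was profiled in 4 groups of 3 mouse samples. The groups were a diet labelled CD, a high-fat diet (HFD), and each diet combined with 2% DSS. DSS is dextran sulfate sodium, a polysaccharide given to rodents to injure the colonic epithelium and provoke colitis. The labels do not spell out CD. Between 21814 and 23236 genes were above 0 in a library, and about 14700000 (CD+DSS replicate 3) to 17900000 (HFD+DSS replicate 3) fragments fell on genes. The first principal component held 26.0% of the variance and separated the libraries by DSS, with scores of 4.75 to 44.8 in the 6 DSS libraries and of -35.6 to -2.65 in the 6 others. HFD+DSS replicate 1 stood apart on the second component (17.5% of variance, score -50.7), and HFD+DSS replicate 3 on the third (13.2%, score 43.2).

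Libraries of 1 group differed in genes that mark position along the gut. Hoxb13 (ENSMUSG00000049604, mm10 chromosome 11, 96194316 to 96197447), a Hox gene expressed toward the anal end of the body axis, was at FPKM 32.9, 61.3 and 28.8 in the CD libraries and at 27.4, 37.8 and 62.8 in the HFD+DSS libraries. In HFD it was at 0.712, 0 and 19.3, and in CD+DSS at 22.6, 0.0336 and 0.122. The mean log2 level of Hoxa13, Hoxb13 and Hoxd13 differed by -1.92 ± 0.92 (SE) in HFD against CD and by 2.39 ± 0.92 in HFD+DSS against CD+DSS. It differed by -2.31 ± 0.92 in CD+DSS against CD and by 2.00 ± 0.92 in HFD+DSS against HFD. Hoxb6, a Hox gene expressed further forward along the body axis, was at 2.17 and 2.82 in CD replicates 1 and 2 and at 24.7 in CD replicate 3. It was at 34.0, 20.7 and 17.1 in HFD, 12.5, 45.5 and 22.5 in CD+DSS, and 11.4, 19.4 and 36.1 in HFD+DSS. HFD+DSS replicate 3 thus had high Hoxb6 beside the highest Hoxb13, so the 2 genes did not mirror each other in every library. The posterior Hox level as a measure of position rests on Hoxa13, Hoxb13 and Hoxd13 alone. Hoxb6, and Hoxb13 as the gene to give by library, were singled out after their values were seen.

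**Figure D1:**
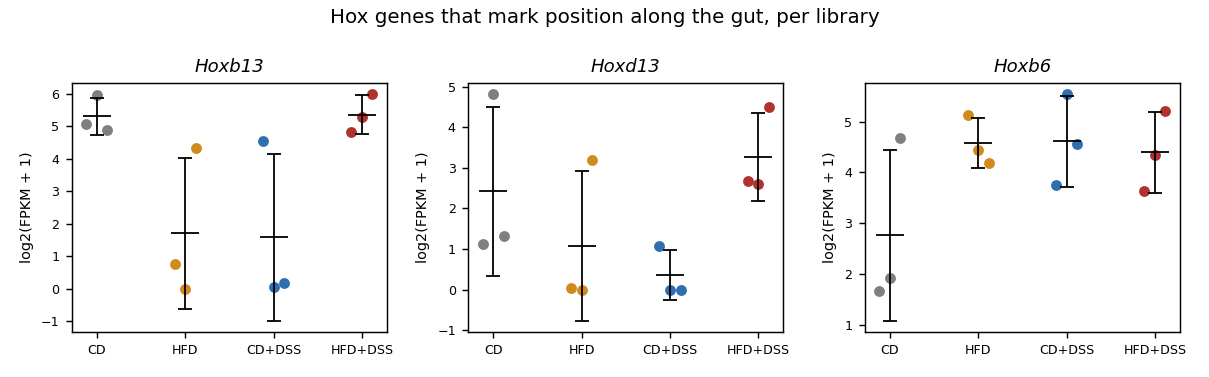
Log2(FPKM + 1) of Hoxb13, Hoxd13 and Hoxb6 in each of the 12 libraries, with the 4 groups on the x axis. Points are libraries, and the dash with bars is the mean ± SD of the log2 values (n = 3); Hoxb13 was at FPKM 27.4 or more in all CD and HFD+DSS libraries and at 22.6 or less in all HFD and CD+DSS libraries.

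Under the CD diet, 10 genes were higher and 2 lower with DSS, among them the epithelial defence genes Reg3g and Saa3, the matrix protease gene Mmp3 and the cytokine signalling genes Socs3 and Il4ra. Reg3g, a secreted antibacterial lectin (ENSMUSG00000030017, chromosome 6, 78466269 to 78468872), rose from FPKM 5.25 ± 6.44 (SD, n = 3) in CD to 393 ± 283 in CD+DSS, a log2 fold change of 6.00 ± 0.86 (SE; limma adjusted p = 0.0390). Mmp3, the matrix metalloproteinase stromelysin-1 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975), rose from 0.707 ± 0.264 to 25.5 ± 19.4, and Socs3, a feedback inhibitor of STAT3 signalling (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047), from 4.523 ± 1.801 to 30.2 ± 8.1. Their log2 fold changes were 3.70 ± 0.39 and 2.52 ± 0.30 (limma adjusted p = 0.0163 and 0.0209). The acute-phase gene Saa3 rose by 3.98 ± 0.61, the actin-capping gene Capg by 1.503 ± 0.212, the NF-kappaB regulator Bcl3 by 1.39 ± 0.17, the interleukin 4 receptor gene Il4ra by 1.26 ± 0.19 and the heat shock gene Hspa1a by 1.81 ± 0.27. St3gal6, a sialyltransferase gene (ENSMUSG00000022747, chromosome 16, 58468125 to 58524243), fell by 1.86 ± 0.25 on the log2 scale (limma adjusted p = 0.0328), and Tceal8 fell by 0.91 ± 0.12. In all, 12 of 14179 genes passed the limma test, 10 higher and 2 lower, with 2149 at an unadjusted p under 0.05 and 15 called by voom on the recovered fragments. The count fell to 0 without CD replicate 1 or without HFD replicate 2, to 1 without CD+DSS replicate 3, to 3 without CD replicate 2 or without CD+DSS replicate 2 and to 6 without HFD replicate 1, and rose to 24 without HFD+DSS replicate 1 and to 33 without CD replicate 3. It was 5 without the filter on low values, and 0 in a fit of the 2 groups alone, with smooth muscle level as a covariate or with posterior Hox level as a covariate.

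Gene groups of inflammation and injury were shifted upward by DSS under CD, and crypt and muscle groups downward. All 10 tested inflammatory cytokines and mediators had positive fold changes (mean log2 1.28; camera adjusted p = 7.50e-06, and adjusted p = 0.518 with an estimated correlation). None of the 10 passed over all genes, and 7 rose when adjusted over the list alone; the inducible nitric oxide synthase gene Nos2 went from 1.39 ± 0.87 to 18.5 ± 2.9 (log2 3.101 ± 0.522). The hypoxia and glycolysis list had a mean of 0.57, with 6 of 17 genes rising when adjusted over the list alone, wound-associated epithelium a mean of 0.74 with 4 of 19, and chemokines a mean of 0.62 with 3 of 24. Fatty acid oxidation and PPAR targets had a mean of 0.55, with 1 of 30 rising when adjusted over the list alone. Stem and crypt-base markers had a mean of -0.45, with 5 of 16 falling when adjusted over the list alone, among their leading members the Wnt target Axin2 (log2 -0.88 ± 0.22). Smooth muscle genes had a mean of -0.55, and 0 of 14 passed when adjusted over the list alone. These 7 lists kept their camera calls when any 1 library was left out, and all 7 were lost with an estimated correlation (adjusted p = 0.518 to 0.561). With posterior Hox level as a covariate they kept the call, with a smaller mean of -0.32 for smooth muscle. Without CD+DSS replicate 2 the mean of fatty acid oxidation and PPAR targets was 0.34.

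The other 16 of the 23 lists that camera called in CD+DSS against CD lost the call in at least 1 fit that left out a library. Upward among them were epithelial defence (mean 0.865), in which Reg3g and Saa3 rose over all genes and 8 genes rose and 4 fell when adjusted over the list alone, and fibroblast and extracellular matrix genes (0.58), of which Mmp3 rose over all genes and 5 of 24 when adjusted over the list alone. The upward lists also held neutrophil markers (0.92), bile acid genes (0.72), MHC class II (0.60), T and NK cell markers (0.57), interferon response (0.37), NRF2 targets (0.31), the nuclear-encoded respiratory chain (0.28) and junction proteins (0.18). Downward were mitochondrially encoded genes (-0.50), proliferation (-0.40), B and plasma cell markers (-0.38), tuft cell markers (-0.37), fatty acid synthesis (-0.21) and circadian clock genes (-0.17). With posterior Hox level as a covariate 6 of the 16 lost the call, with means of 0.51 for bile acid genes, 0.49 for epithelial defence, 0.15 for junction proteins, -0.036 for fatty acid synthesis, -0.082 for mitochondrially encoded genes and 0.099 for B and plasma cell markers. Proliferation (-0.22), tuft cell markers (-0.73) and neutrophil markers (1.39) kept the call with means that moved by over 1.5 times. Adjusted p with an estimated correlation was 0.518 to 0.807 for the 15 upward lists and 0.518 to 0.661 for the 8 downward lists.

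**Figure D2:**
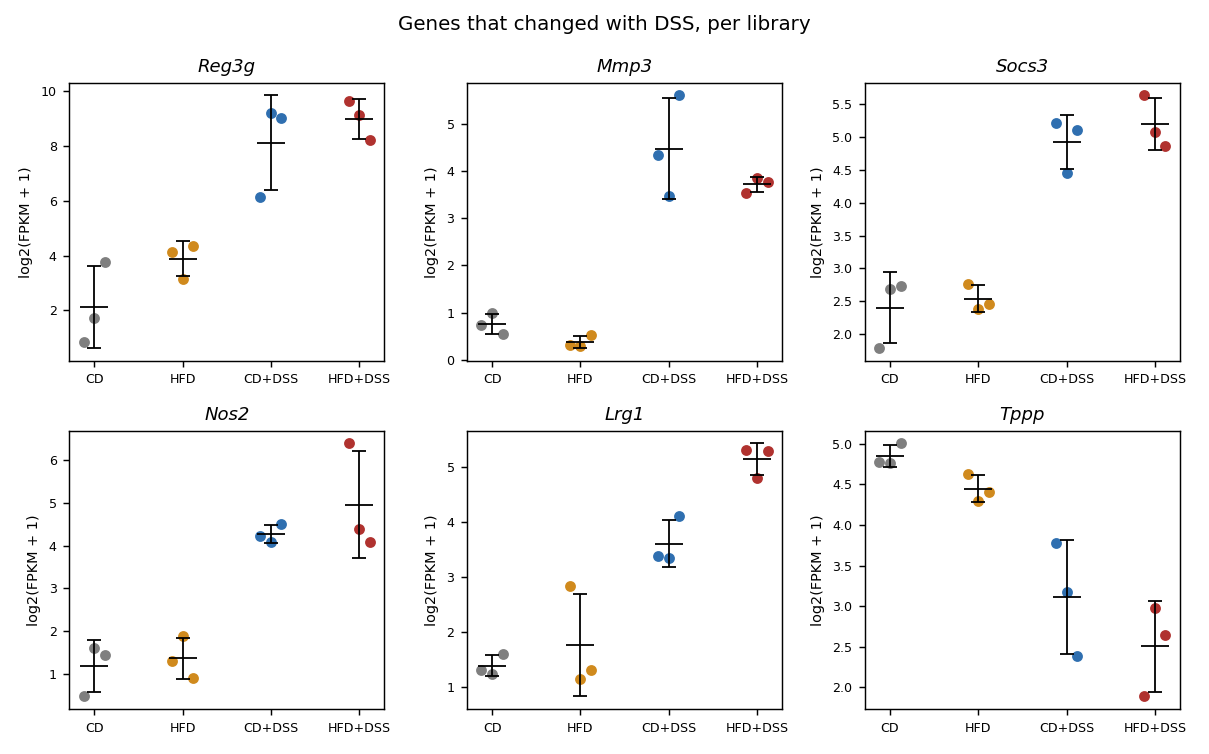
Log2(FPKM + 1) of Reg3g, Mmp3, Socs3, Nos2, Lrg1 and Tppp in each library, with the 4 groups on the x axis. Points are libraries, and the dash with bars is the mean ± SD of the log2 values (n = 3); mean FPKM of Socs3 was 4.52 in CD and 4.84 in HFD, and 30.2 in CD+DSS and 36.6 in HFD+DSS.

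Under HFD, 35 genes were higher and 13 lower with DSS, among them the defence genes Reg3g and Nos2, the chloride channel regulator gene Clca4b and the acute-phase gene Lrg1. Clca4b, a chloride channel regulator of the epithelium (ENSMUSG00000074195, chromosome 3, 144910921 to 144932529), rose from 4.33 ± 2.53 in HFD to 556 ± 603 in HFD+DSS (log2 6.24 ± 0.72; limma adjusted p = 0.00842). Lrg1, a secreted glycoprotein of the acute phase (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), rose from 2.93 ± 2.75 to 34.5 ± 6.7 (log2 3.37 ± 0.38; limma adjusted p = 0.00842). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) rose from 1.67 ± 0.92 to 39.5 ± 37.5 (log2 3.59 ± 0.52), and Reg3g, Mmp3 and Socs3 rose by log2 5.12 ± 0.86, 3.34 ± 0.39 and 2.66 ± 0.30. The phospholipase gene Pla2g2a rose by 3.07 ± 0.45 and the protease inhibitor gene Slpi by 2.64 ± 0.45. Tppp, a microtubule-binding protein gene (ENSMUSG00000021573, chromosome 13, 74009407 to 74035753), fell from 20.9 ± 2.6 to 4.95 ± 2.12 (log2 -1.94 ± 0.33; limma adjusted p = 0.0391). The matrix proteoglycan gene Ogn fell by 1.71 ± 0.31, the surface glycoprotein gene Cd24a by 1.43 ± 0.25 and the cholinesterase gene Bche by 1.16 ± 0.20. In all, 48 genes passed the limma test, 35 higher and 13 lower, with 1924 at an unadjusted p under 0.05 and 48 called by voom. Leaving out a library gave 1 (HFD replicate 2), 3 (HFD replicate 1), 10 (CD replicate 2 or HFD+DSS replicate 1), 16 (HFD+DSS replicate 3), 17 (HFD replicate 3), 19 (CD replicate 1), 26 (CD replicate 3), 29 (CD+DSS replicate 3) or 78 (HFD+DSS replicate 2). The count was 10 without the filter, 12 in a fit of the 2 groups alone and 1 with posterior Hox level as a covariate.

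Inflammatory cytokines and mediators again had a positive mean (1.22; camera adjusted p = 7.50e-06, and adjusted p = 0.553 with an estimated correlation), with Nos2 rising over all genes and 6 of 10 when adjusted over the list alone. Epithelial defence had a mean of 1.24, with Reg3g and Nos2 rising over all genes and 10 of 19 when adjusted over the list alone, and the same adjusted p = 0.553 with an estimated correlation. T and NK cell markers had negative fold changes in all 17 members (mean -0.64; camera adjusted p = 5.03e-06, and adjusted p = 0.699 with an estimated correlation), and 1 fell when adjusted over the list alone, the cytotoxic granule gene Nkg7 being at 10.5 ± 2.0 in HFD and 3.55 ± 0.89 in HFD+DSS. These 3 lists kept their calls when any 1 library was left out, and the other 10 did not. Among those 10, neutrophil markers had a mean of 1.73, enteric neurons and glia 0.61, hypoxia and glycolysis 0.49 and wound-associated epithelium 0.47. Adipocyte markers had a mean of -1.02, tuft cell markers -0.42, stem and crypt-base markers -0.30, goblet cell markers -0.25, circadian clock genes -0.22 and autophagy machinery -0.12. Some of these means moved when a library was left out. That of enteric neurons and glia was 0.18 without HFD+DSS replicate 3. Without HFD+DSS replicate 1 the mean was 0.28 for hypoxia and glycolysis and -0.65 for adipocyte markers. The glial filament gene Gfap rose from 1.02 ± 0.10 to 7.40 ± 4.02 (log2 1.91 ± 0.32; limma adjusted p = 0.0391), and the monocyte surface gene Cd14 from 23.02 ± 2.48 to 58.3 ± 4.8 (log2 1.30 ± 0.18; limma adjusted p = 0.0175). With posterior Hox level as a covariate 5 lists lost the call, with means of 0.27 for wound-associated epithelium (adjusted p = 0.174), -0.15 for circadian clock genes (0.218), -0.10 for tuft cell markers (0.503), -0.064 for goblet cell markers (0.582) and -0.047 for autophagy machinery (0.503). The autophagy call was also lost without HFD+DSS replicate 1 (adjusted p = 0.177), HFD replicate 1 (0.117) or HFD+DSS replicate 3 (0.0817). Adjusted p with an estimated correlation was 0.553 to 0.721 for the 6 upward lists and 0.553 to 0.792 for the 7 downward lists.

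Reg3g, Mmp3, Socs3, Bcl3 and Sbno2 rose under both diets, against 0.0247 genes expected in common if the 2 sets of calls were independent. Sbno2 was named after its values were seen. No called gene fell under both diets or moved in opposite directions. Across the 14179 genes the DSS fold changes under CD and under HFD correlated with Pearson r = 0.369 and Spearman rho = 0.448, where genes are not independent replicates. The 12 genes called under CD had a median absolute log2 fold change of 1.66 under CD and 1.13 under HFD, with the same sign in all 12. The 48 called under HFD had a median absolute value of 1.63 under HFD and 0.86 under CD, with the same sign in 42. Each set was selected by its test in 1 diet, which by itself favours larger values in that diet. The 2 comparisons share no library, but both use 1 variance estimate per gene from the fit of all 12. A gene with a low estimate is favoured in both, so the expected number in common is too low by an unknown amount.

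Between HFD and CD without DSS, camera called gene groups of lipid handling at the preset correlation, and no single gene passed the test. Fatty acid oxidation and PPAR targets, the genes that nuclear receptors of fatty acids switch on, had positive fold changes in 29 of 30 members (mean log2 0.75; camera adjusted p = 8.20e-22, and adjusted p = 0.258 with an estimated correlation). None passed over all genes, and 7 rose when adjusted over the list alone. Angptl4, an inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830), was at 1.01 ± 0.60 in CD and 5.49 ± 2.50 in HFD (log2 1.64 ± 0.31; limma adjusted p = 0.711). Vnn1, a pantetheinase gene, was at 1.12 ± 0.49 and 13.4 ± 6.5 (log2 2.67 ± 0.56), and the fatty acid transporter gene Cd36 at 5.79 ± 2.24 and 22.4 ± 9.9. Adipocyte markers were positive in all 13 members (mean 1.44; camera adjusted p = 2.02e-16, and adjusted p = 0.258 with an estimated correlation), 9 of them rising when adjusted over the list alone. The fatty acid binding gene Fabp4, expressed mainly by fat cells, was at 5.94 ± 4.57 in CD and 19.8 ± 8.2 in HFD. Bile acid receptors, targets and transport genes had a mean of 0.99, with 12 of 13 positive and 5 rising when adjusted over the list alone (adjusted p = 0.408 with an estimated correlation). The bile acid exporter subunit gene Slc51a was at 5.59 ± 7.63 and 28.6 ± 13.8 and the bile acid receptor gene Nr1h4 at 35.2 ± 12.4 and 54.4 ± 11.2. T and NK cell markers were positive in all 17 (mean 0.63; adjusted p = 0.408 with an estimated correlation), and 2 rose when adjusted over the list alone, with Nkg7 at 3.66 ± 2.06 and 10.5 ± 2.0. Cholesterol synthesis and uptake genes had a mean of -0.24, with 2 of 22 positive and 0 passing when adjusted over the list alone. Posterior Hox genes were lower in HFD than in CD, as given above, beside each of these groups.

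Epithelial defence (mean -0.45), goblet cell markers (-0.42), exocrine pancreas markers (-0.73) and the unfolded protein response (-0.17) were also called downward by camera in HFD against CD. Only 3 of 12 exocrine pancreas genes were tested, and 1 of them, Zg16, is also in the goblet cell list. With posterior Hox level as a covariate the mean of epithelial defence was -0.76. None of these 4 kept the call without CD replicate 3, where adjusted p reached 0.165, 0.585, 0.165 and 0.966, and adjusted p with an estimated correlation over the 5 downward lists was 0.258 to 0.968. The goblet cell gene Spink4 was at 884.0 ± 501.4 in CD and 319 ± 100 in HFD, and the elastase gene Cela1 at 48.7 ± 16.9 and 17.7 ± 3.6. Of single genes, 0 passed the limma test, 588 had an unadjusted p under 0.05 where chance gives 709, and voom called 0. The smallest p values belonged to 9030619P08Rik (log2 -2.45 ± 0.34) and the phospholipase gene Pla2g2f (-2.17 ± 0.31), each with limma adjusted p = 0.130. The count was 2 without CD replicate 3 and 1 without CD+DSS replicate 3.

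Among samples given DSS, the series asks whether HFD worsens colitis and lowers autophagy. The values here are transcript levels, which do not measure autophagic activity or the severity of colitis. The autophagy machinery list had positive fold changes in 4 of 40 members and negative ones in 36, with a mean of -0.19 on the log2 scale (camera adjusted p = 5.25e-05, and adjusted p = 0.872 with an estimated correlation), and 0 genes passed over all genes or when adjusted over the list alone. Sqstm1, the autophagy receptor p62, was at 92.0 ± 19.4 in CD+DSS and 67.3 ± 8.9 in HFD+DSS (log2 -0.43 ± 0.18; limma adjusted p = 0.740), and the lipid-transfer gene Atg2a at 8.42 ± 0.41 and 5.51 ± 1.74. Map1lc3b (log2 -0.07 ± 0.14), Becn1 (-0.28 ± 0.12), Atg5 (-0.15 ± 0.21), Atg7 (-0.04 ± 0.12) and Atg16l1 (0.03 ± 0.15) did not pass. Inflammatory genes did not pass either, with Il1b at 14.2 ± 11.3 in CD+DSS and 5.28 ± 3.68 in HFD+DSS (log2 -1.22 ± 0.55; limma adjusted p = 0.749), Tnf at 3.72 ± 0.67 and 4.31 ± 2.36, Lcn2 at 7.11 ± 6.27 and 4.08 ± 1.21, and S100a9 at 7.82 ± 7.58 and 8.01 ± 6.97. The inflammatory cytokine list had a mean of -0.19 and was not called. The autophagy call held when any 1 library was left out (highest adjusted p = 0.0195, with a mean of -0.11, without CD+DSS replicate 2) and was lost with posterior Hox level as a covariate (mean -0.10, adjusted p = 0.0540), and posterior Hox genes were higher in HFD+DSS than in CD+DSS.

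Goblet cell markers had a mean of -0.58 in HFD+DSS against CD+DSS, and 7 of 17 fell when adjusted over the list alone (camera adjusted p = 3.63e-06, and adjusted p = 0.872 with an estimated correlation, as for each of the 11 lists called here). Muc2, the main secreted mucin of the colon (ENSMUSG00000025515, chromosome 7, 141690340 to 141754693), was at 936 ± 304 in CD+DSS and 357 ± 49 in HFD+DSS (log2 -1.35 ± 0.31; limma adjusted p = 0.700), and the goblet cell transcription factor gene Spdef at 46.7 ± 2.4 and 22.6 ± 6.2. Smooth muscle genes were positive in all 14 members (mean 0.70), with 0 passing when adjusted over the list alone, and the smooth muscle actin gene Acta2 was at 299 ± 87 in CD+DSS and 590 ± 332 in HFD+DSS, with 973 in HFD+DSS replicate 3, without which the mean of the list was 0.37. Enteric neurons and glia were positive in all 13 (mean 0.55), and the call was lost without HFD+DSS replicate 3 (adjusted p = 0.193). T and NK cell markers had a mean of -0.59, with 5 falling when adjusted over the list alone, and the call was lost without CD+DSS replicate 1 (adjusted p = 0.0864). The cytotoxic T cell gene Cd8a was at 7.10 ± 3.04 and 2.67 ± 0.98 and Gzmb at 21.9 ± 13.7 and 5.88 ± 1.57. Proliferation genes had a mean of 0.34, lost without CD+DSS replicate 2 (adjusted p = 0.195), and junction proteins a mean of -0.30, lost without HFD+DSS replicate 3 (adjusted p = 0.0761). Fibroblast and matrix genes (-0.40), lysosome genes (-0.14), wound-associated epithelium (-0.37) and mitochondrially encoded genes (0.39) were each lost in at least 3 of the fits that left out a library. With posterior Hox level as a covariate the mean was -0.35 for goblet cell markers, 0.15 for proliferation and -0.61 for wound-associated epithelium, which stayed called, and -0.047 for mitochondrially encoded genes, which did not. Of single genes, 0 passed the limma test, with 938 at an unadjusted p under 0.05 and 0 called by voom. The count was 1 without CD+DSS replicate 1 and 2 without the filter, and the smallest p belonged to Hspa1a (log2 -1.75 ± 0.27; limma adjusted p = 0.505).

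**Figure D3:**
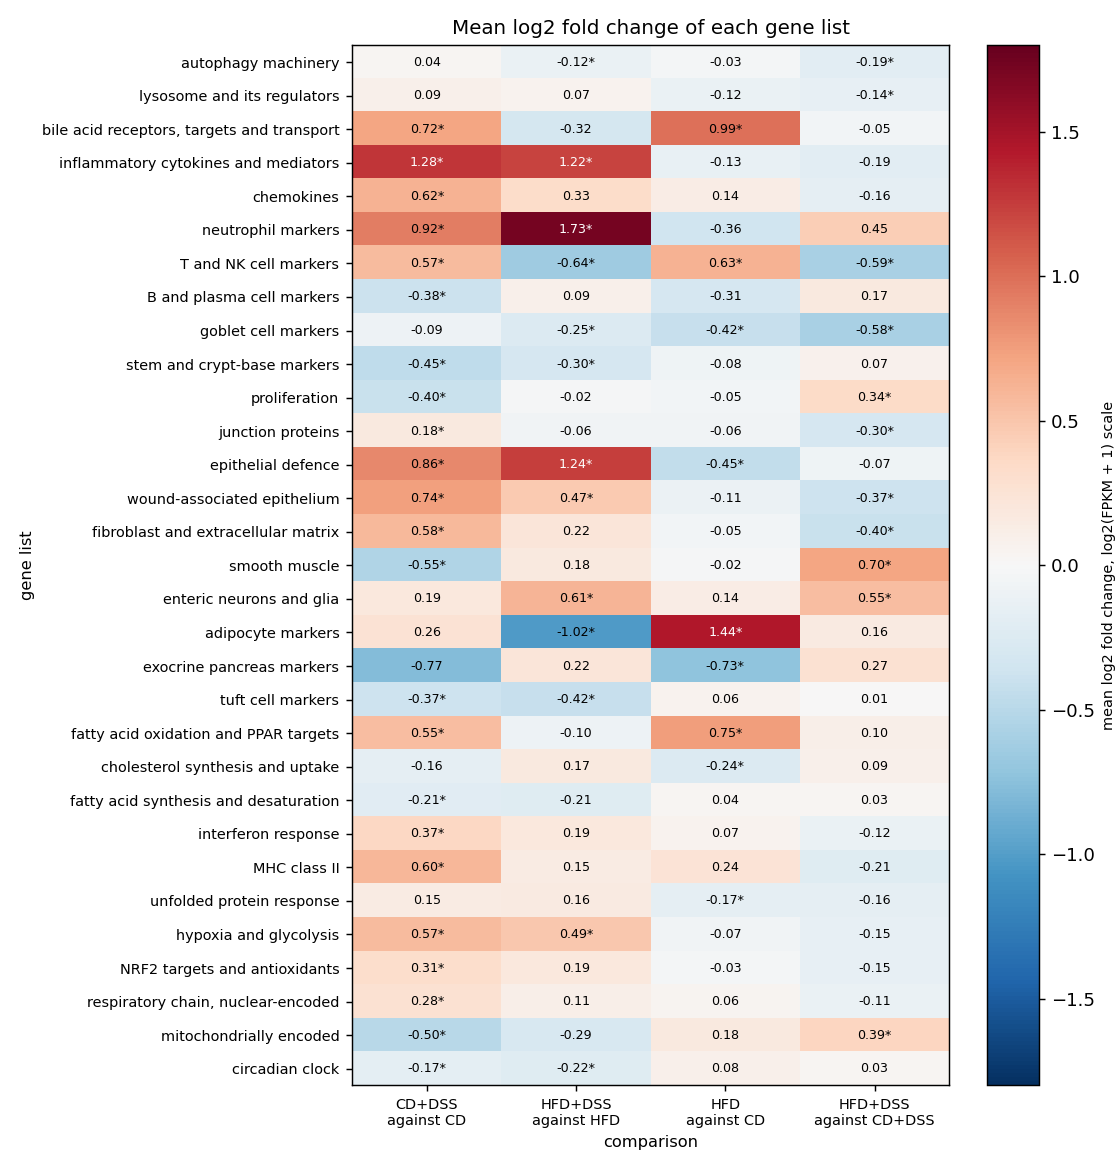
Mean log2 fold change, on the log2(FPKM + 1) scale, of the 31 gene lists that camera called in at least 1 of the 4 comparisons between groups, with lists in rows and comparisons in columns. Colour and number give the mean and an asterisk marks camera adjusted p under 0.05 at the preset correlation; adipocyte markers had a mean of 1.44 in HFD against CD and -1.02 in HFD+DSS against HFD.

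Averaged over DSS, the diet effect had 0 genes past the limma test, 662 at an unadjusted p under 0.05 and 0 called by voom. The smallest p belonged to Hspa1a (log2 -1.24 ± 0.19), the aminopeptidase gene Enpep (0.79 ± 0.13), the neutrophil and epithelial surface gene Cd177 (-1.29 ± 0.23) and Angptl4 (1.24 ± 0.22), each with limma adjusted p = 0.329. Cd177 was at 109 ± 19 in CD and 39.4 ± 6.3 in HFD, and at 91.0 ± 35.8 and 41.9 ± 19.5 with DSS. Camera called 14 lists, among them fatty acid oxidation and PPAR targets (mean 0.43, 5 rising when adjusted over the list alone), adipocyte markers (0.80, 2 rising), goblet cell markers (-0.50, 6 falling) and autophagy machinery (-0.11, 0 passing), with adjusted p of 0.707 to 0.882 with an estimated correlation. The first 2 were called in HFD against CD (means 0.75 and 1.44) and not in HFD+DSS against CD+DSS, so their averages rest mainly on the samples without DSS. Across genes the diet fold changes without and with DSS correlated with Pearson r = -0.143 and Spearman rho = -0.018. The mean of autophagy machinery was -0.074 without CD+DSS replicate 2. Its call held when any 1 library was left out (highest camera adjusted p = 0.0280). With posterior Hox level as a covariate its mean was -0.10, and it stayed called at the preset correlation (camera adjusted p = 0.00095). The posterior Hox difference averaged over DSS was 0.24 ± 0.65, so the covariate could move this contrast little. The count of genes was 2 without the filter and 1 with smooth muscle level as a covariate.

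Whether the DSS response differed between diets was tested by the interaction. No gene passed the limma test, with 769 at an unadjusted p under 0.05 and 0 called by voom. Nkg7 had an interaction of -2.59 ± 0.39 and Pla2g2f of 2.84 ± 0.43 on the log2 scale (limma adjusted p = 0.174 each), and the chemokine gene Ccl4 of -1.799 ± 0.410. Autophagy genes were not called singly, with Sqstm1 at -0.46 ± 0.25 and Becn1 at -0.29 ± 0.17. The colonic hormone gene Insl5 had an interaction of 5.42 ± 1.46 (limma adjusted p = 0.560). Camera called 14 lists at the preset correlation, with adjusted p of 0.735 to 0.905 with an estimated correlation. The posterior Hox genes had an interaction of 4.30 ± 1.30. The count was 3 without CD replicate 3, 1 without CD+DSS replicate 1 and 1 without the filter.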

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

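Apart from the interaction tests, the tests below were chosen after the pattern they address was seen; for the fat tissue test of the adipocyte genes and the test of position along the colon for the fatty acid genes, the values that the test measures had not been seen.

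The DSS effect differed between the diets in 14 gene lists by camera on the interaction at the preset correlation, with adjusted p of 0.735 to 0.905 with an estimated correlation. The mean interaction on the log2 scale was -1.2751 for adipocyte markers, -1.2147 for T and NK cell markers, -1.0324 for bile acid genes, -0.6457 for fatty acid oxidation and PPAR targets, -0.4533 for MHC class II, -0.3589 for fibroblast and matrix genes, -0.2417 for junction proteins, -0.1687 for the nuclear-encoded respiratory chain and -0.1541 for autophagy machinery. It was 0.9986 for exocrine pancreas markers, 0.7285 for smooth muscle, 0.4144 for enteric neurons and glia, 0.386 for proliferation and 0.3364 for cholesterol synthesis and uptake. Of these lists, 6 kept the call when any 1 library was left out, though the mean was -0.8042 for adipocyte markers without CD replicate 2, -0.6563 for bile acid genes without CD+DSS replicate 2, and 0.4747 and 0.3912 for smooth muscle without HFD replicate 3 and without HFD+DSS replicate 3. With posterior Hox level as a covariate 7 of the 14 lists lost the call. The mean moved to -0.0022 for autophagy machinery (adjusted p = 0.875), 0.0404 for proliferation (0.541), 0.196 for enteric neurons and glia (0.316) and 0.315 for smooth muscle (0.123). It was -0.199 for junction proteins (0.260), -0.354 for fibroblast and matrix genes (0.0636) and 0.953 for exocrine pancreas markers (0.0565), close to the values without the covariate. Among the lists that stayed called, the mean of bile acid genes was -0.645, that of MHC class II -0.766 and that of the respiratory chain -0.276. Without HFD+DSS replicate 3 the mean of enteric neurons and glia was -0.0078.

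In 15 of the 406 genes that the naming rule gives over all contrasts, the libraries of the 2 diets did not overlap, in opposite directions without and with DSS. On the log2 scale the interaction was -2.59 for Nkg7, -3.17 for Gzma, -1.97 for Cd8a, -1.12 for Lck, -1.8 for Ccl4, -1.25 for Ccl9 and -1.99 for Ndrg1. It was 3.63 for Pla2g2a, 2.95 for Trgj1, 2.93 for 9030619P08Rik, 2.12 for Wfdc18, 1.86 for Slc1a1, 1.84 for St3gal6, 0.99 for Cd14 and 0.68 for Tceal8. This separation was not tested as such, and 0 of the 15 passed the limma interaction test, which had 769 genes at an unadjusted p under 0.05 and 0 calls by voom. The rule favours genes with small p, and over all genes 71 of 14179 separated in this way, where chance gives 70.9 (0.5%).

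Adipocyte markers were higher in HFD than in CD by 1.436 ± 0.584 (SE of the list score) and fatty acid oxidation and PPAR targets by 0.749 ± 0.239. Fat tissue carried with the colon is a candidate explanation for the adipocyte markers. The mean of Adipoq, Plin1 and Cidec and that of Retn, Cfd and Car3 deviated together within groups over the 12 libraries. Pearson r was 0.951 and Spearman rho 0.930 (permutation p = 8e-04 each, near the smallest that shuffling within groups of 3 can give, 2 such relations computed). Pearson r was 0.935 when the 2 libraries of largest deviation were dropped, with group means still taken over all 12. Genes of 1 cell type vary together whenever its share varies, so this cannot tell carried fat from fat cells within the bowel wall. Adipoq was at FPKM 4.80 ± 5.96 in CD and 22.4 ± 13.6 in HFD, Cfd at 30.7 ± 34.0 and 85.6 ± 60.2, and Car3 at 14.8 ± 15.3 and 65.3 ± 37.2. None of the 13 tested adipocyte genes is in another list, and 8 of them were at FPKM 1 or more in every CD library. Fat tissue as the only source of the fatty acid pattern was argued against by 7 members made mainly by enterocytes, which differed by 1.356 ± 0.397. These 7 were chosen after values had been seen, and for the other members of the list fat tissue stays open. A different stretch of colon may contribute, as posterior Hox genes differed by -1.915 ± 0.916, just over 2 SE, and the fatty acid list differed by 0.669 ± 0.314 with their level as a covariate; a single library stays open (0.965 ± 0.574 for adipocyte markers without CD replicate 2, 0.567 ± 0.241 for fatty acid genes without HFD replicate 3), as does the diet itself, which was not tested apart from these.

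Smooth muscle genes were higher in HFD+DSS than in CD+DSS by 0.704 ± 0.363. A different share of bowel wall layers in the samples is a candidate explanation, since the smooth muscle score and that of enteric neurons and glia deviated together within groups over the 12 libraries (Pearson r = 0.792 and Spearman rho = 0.895, permutation p = 0.00917 and 0.0123). Pearson r was 0.648 when the 2 libraries of largest smooth muscle deviation were dropped. Group means were still taken over all 12, so the dropped libraries still shaped that value. None of the 14 tested smooth muscle genes is in another list, 12 of them were at FPKM 1 or more in every CD library, and Acta2 was at 299 ± 87 in CD+DSS and 590 ± 332 in HFD+DSS. A single library cannot be excluded, with 0.367 ± 0.328 without HFD+DSS replicate 3, nor can a different stretch of colon, with 0.474 ± 0.513 when posterior Hox level was a covariate. An effect of diet on the bowel wall under DSS stays open and was not tested apart from these.

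T and NK cell markers were higher in HFD than in CD without DSS and lower with DSS, with a difference of differences of -1.215 ± 0.427. For lymphoid tissue caught in some samples, the difference of differences of 9 B cell genes lay 1.859 ± 0.882 above that of the T and NK list. This passed the bound of 2 SE by a thin margin, too thin to decide with 3 samples per group. By themselves the B cell genes gave 0.644 ± 0.922, with an SE larger than the value. The paired difference was also taken as the test after both values had been seen, so lymphoid tissue stays open. For the difference of differences, a single library was argued against by the value nearest 0 when each was left out, -0.929 ± 0.36 without CD+DSS replicate 1. Relative to their SE, the weakest values were -1.047 ± 0.446 without CD replicate 1 and -1.03 ± 0.437 without HFD+DSS replicate 3. Each of these lay only a little over 2 SE from 0, so the margin is thin. For the lower level with DSS taken alone, a single library stays open. Without CD+DSS replicate 1 the list mean in HFD+DSS against CD+DSS went from -0.588 to -0.302, and the call was lost (camera adjusted p = 0.0864). The difference of differences with posterior Hox level as a covariate was -1.33 ± 0.702, no smaller than without it and still called by camera at the preset correlation (adjusted p = 5.63e-16), but within 2 SE of 0, so a different stretch of colon is not excluded. A diet effect that depends on DSS also stays open, as untested; none of the 17 tested genes is in another list, and 12 were at FPKM 1 or more in every CD library.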

How the results depend on the processing

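Sample weights, voom, the smooth muscle and posterior Hox covariates and the contrast of DSS averaged over diets were chosen after the data were seen.

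No named gene changed sign where it was called in the main fit or under the alternative. Sign changes of genes called in neither were not counted, and a count of genes has no sign to reverse. Of the called lists, 3 changed the sign of their mean in 1 setting each: with posterior Hox level as a covariate B and plasma cell markers in CD+DSS against CD went from -0.3845 to 0.099 and mitochondrially encoded genes in HFD+DSS against CD+DSS from 0.3898 to -0.047, and without HFD+DSS replicate 3 the interaction of enteric neurons and glia went from 0.4144 to -0.0078; the cause was not tested. Among the named genes under the alternatives, 3349 values stayed on their side of the threshold, 428 were no longer past it and 20 newly passed. These values cover the named genes that were called and most of the fixed genes whatever their p. The 3349 therefore include fixed genes that were called in neither fit, and do not measure how many calls held.

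Without the filter, with more genes tested, 5 genes were called in CD+DSS against CD, 10 in HFD+DSS against HFD, 2 in HFD+DSS against CD+DSS, 2 for the averaged diet, 1 for the interaction and 173 for averaged DSS. With only the 2 compared groups, and so fewer samples, the DSS counts were 0 under CD and 12 under HFD. A replicate block gave 2, 12 and 162 for DSS under CD, under HFD and averaged; replicate numbers did not pair the libraries, as the 18 same-number pairs had correlations of -0.462 to 0.204 (median -0.1085, against 0.042 for other pairs). A 2-fold threshold left 121 of the 389 averaged DSS calls by its construction.

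Sample weights called 2591 genes for DSS under CD, 937 under HFD, 96 for HFD against CD, 7 for HFD+DSS against CD+DSS, 50 for the averaged diet, 23 for the interaction and 4222 for averaged DSS. In 20 random regroupings the highest weighted count was 1834 to 4181 by contrast, with medians of 0 to 1, and the highest with equal weights was 1035 for the averaged diet, 480 for HFD+DSS against CD+DSS and 0 to 3 elsewhere. The real weighted counts were above every regrouping for DSS under CD (1834) and averaged DSS (2881) and not for the other 5 contrasts. Smooth muscle level as a covariate gave 0 genes for DSS under CD and 1 for the averaged diet. Posterior Hox level as a covariate gave 0 and 1 for DSS under CD and HFD, and 14 lists for HFD against CD in place of 9; the cause was not tested.

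Camera with an estimated correlation called 0 lists in every contrast, against 23 for DSS under CD, 13 under HFD, 9 for HFD against CD, 11 for HFD+DSS against CD+DSS, 14 for the averaged diet, 14 for the interaction and 15 for averaged DSS. Fry called 0, and 5 for averaged DSS. The correlation of the DSS fold changes between diets was 0.2806 with a pseudocount of 0.1 and 0.369 with 1; the cause was not tested.

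Leaving out 1 library, with fewer samples, gave 0 (without CD replicate 1 or HFD replicate 2) to 33 genes (CD replicate 3) for DSS under CD, and 1 (HFD replicate 2) to 78 (HFD+DSS replicate 2) under HFD. It gave 0 to 2 for HFD against CD (CD replicate 3), 0 to 1 for HFD+DSS against CD+DSS (CD+DSS replicate 1), 0 for the averaged diet in every fit, 0 to 3 for the interaction (CD replicate 3) and 114 (HFD replicate 2) to 479 (CD replicate 3) for averaged DSS. Lists called ranged from 16 to 24 for DSS under CD and 5 (HFD+DSS replicate 1) to 16 under HFD. They ranged from 7 to 16 (HFD replicate 3) for HFD against CD, 6 (HFD+DSS replicate 3) to 18 (HFD+DSS replicate 1) for HFD+DSS against CD+DSS, 10 to 17 for the averaged diet, 11 to 17 for the interaction and 13 to 21 for averaged DSS. The correlation between diets ranged from 0.3041 to 0.4343. Lists that kept the call in every such fit numbered 7 of 23, 3 of 13, 5 of 9, 3 of 11, 7 of 14, 6 of 14 and 9 of 15 in the same order of contrasts.

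Of 10 splits of the 6 libraries, too few for a share under 0.05, the real one called 12 genes for DSS under CD (highest other 0), 48 under HFD (3), 0 for HFD against CD (0) and 0 for HFD+DSS against CD+DSS (4), so that 1, 1, 10 and 10 splits called as many. For averaged DSS 1 of 100 drawn splits, the real one, called as many (389, highest other 53). Chance is unlikely for this count but not excluded, since 1 of 100 is the smallest share that these splits can give. The contrast was also added after the data were seen. For the averaged diet (highest other 3) and the interaction (26) all 100 did. Where the real count is 0 every split reaches it, so those 4 counts of splits decide nothing.

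Median-ratio scaling changed next to nothing, as the deposited values already carried it (390 genes for averaged DSS, and the planned counts as before), so it tested nothing. Depth of 14700000 to 17900000 fragments over genes limits the low genes, and 14179 of 54532 passed the filter.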

Other observations

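Averaged over the diets, a contrast added after the data were seen, DSS changed 389 of 14179 genes by limma, 265 upward and 124 downward, and 462 by voom. Reg3b, Lcn2, Tnf, Axin2 and Jchain, which passed under neither diet by itself, passed here, as did Gfap, which had passed under HFD. Reg3b rose by 6.30 ± 0.87 (SE) on the log2 scale, Lcn2 by 1.92 ± 0.28, Tnf by 1.21 ± 0.20 and Gfap by 1.57 ± 0.23, with limma adjusted p of 0.00773, 0.00825, 0.0127 and 0.00825. The Wnt target gene Axin2 fell by 0.89 ± 0.16 (limma adjusted p = 0.0162) and the antibody joining chain gene Jchain by 1.35 ± 0.32 (limma adjusted p = 0.0481), while Il1b did not pass (1.08 ± 0.39; limma adjusted p = 0.138). The count was 123 without CD replicate 1, 146 without CD replicate 2, 205 without HFD replicate 1, 114 without HFD replicate 2, 210 without CD+DSS replicate 1 and 221 without CD+DSS replicate 3. It was also lower without the filter and with a replicate block, as given in the section on processing.

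In this contrast camera called 15 lists, 10 upward and 5 downward, and 5 of them also by fry. Those 5 were inflammatory cytokines and mediators (mean 1.25, 5 rising over all genes and 8 when adjusted over the list alone; fry adjusted p = 0.0129), epithelial defence (1.05, 7 and 11; 0.0191), hypoxia and glycolysis (0.53, 2 and 10; 0.0235), stem and crypt-base markers (-0.38, 3 and 9 falling; 0.0300) and circadian clock genes (-0.20, with 7 falling when adjusted over the list alone; 0.0191). Each of the 5 kept its camera call when any 1 library was left out. With an estimated correlation camera gave adjusted p of 0.473 to 0.783 for the 15 lists.

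Camera called 6 lists in no contrast. The lowest adjusted p over the planned contrasts was 0.0527 for sex-specific genes (CD+DSS against CD, mean -0.31), 0.205 for endothelium (HFD+DSS against HFD, -0.20), 0.281 for enteroendocrine markers (HFD+DSS against HFD, 0.36), 0.293 for absorptive colonocyte markers (HFD against CD, -0.24), 0.352 for monocyte and macrophage markers (HFD+DSS against CD+DSS, -0.19) and 0.462 for haemoglobin and red cell genes (HFD+DSS against CD+DSS, 0.26).

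Il6 and Fgf15 were too low to be tested. Il6 was at FPKM 0, 0 and 0.0494 in CD, 0.0259, 0.0700 and 0 in HFD, 0.169, 0.122 and 1.52 in CD+DSS, and 0.162, 0.510 and 0.345 in HFD+DSS. Fgf15, the bile-acid-induced hormone gene of the ileum, reached at most 0.0685 in any library.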
